A study of Mus musculus with 24 samples.

How the data were processed

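RNA of the cortex of 24 mice was sequenced, 1 library per mouse, in 4 groups of 6. The genotype label was either control or Abca7, and the stimulus label was either none or LPS (lipopolysaccharide, a component of the outer membrane of Gram-negative bacteria that triggers innate immune signalling). The series design text describes the mice with the Abca7 label as heterozygous for Abca7 and says that LPS was injected; the dose, the route and the time between injection and collection are not given in the sources used here. Each library title carries a different number, taken here as the number of the animal, so the 6 libraries of a group were treated as 6 animals. Replicate numbers in the text only name libraries in the order of the series and pair nothing between groups.

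Per the labels' protocols, cortical tissue was lysed in TRIzol and total RNA was purified with a DNase step and an RNeasy mini kit. Per the series design text, libraries were sequenced on an Illumina HiSeq 4000 and gene counts were made with MAP-RSeq 2.1.1, an RNA-seq workflow of the Mayo Clinic. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to the mouse genome mm10. The annotation release, the strand setting of the counting, the treatment of reads with several matches and the enrichment or depletion step of library preparation are not given in the sources used here. The authors deposited a table of raw read counts per gene, whole numbers with no normalization, for 43346 genes with their coordinates. A set of 3 genes had no symbol and held 0.00824% of all counts; they have gene identifiers and stayed in the tests. A set of 131 genes carried a symbol that another gene also has, and genes were therefore followed by identifier. All columns of the table belong to libraries of the series.

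Coordinates in the text are those of the deposited table, on mm10. For overlaps and shared sequence, the annotation GENCODE M21 was used, which lies on the same genome build but may not be the release behind the table. Of the 43346 identifiers, 42462 (97.96%) occur in it, and 33460 of those (78.8%) have identical coordinates. Because the counting may have ignored strand, counts of a gene that overlaps another on either strand cannot be divided between them. For each named gene and each list member, the share of its 50-base sequences that also occur in transcripts of another gene was computed, since reads from shared sequence could be dropped or assigned to the wrong gene.

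Genes were kept with filterByExpr by group, which left 21891 genes that held at least 99.96% of the counts of each library. Library sizes were scaled with TMM factors. All 24 libraries entered a single fit with 1 coefficient per group in edgeR 4.0.16 with R 4.3.3, and the quasi-likelihood F test was run for 5 contrasts, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The contrasts were the LPS effect in control mice, the LPS effect in mice labelled Abca7, the genotype effect without LPS, the genotype effect under LPS, and the interaction, which is the difference between the LPS effects. All tests were two-sided. Adjusted p-values are from this test unless another tool is named. Levels of single libraries are log2 CPM (counts scaled to a common library total, TMM factors included) with a prior count of 2, and means of CPM use no prior count. The standard error beside a log2 fold change is the fold change divided by the square root of the F statistic of the same test. Single values were compared between groups of 6 with an exact permutation test, which can give no p below 0.00216.

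A set of 25 pathway lists and 15 cell-type marker lists was fixed before the data were examined. The pathway lists covered proinflammatory genes (cytokines, chemokines and NF-kB feedback), interferon-stimulated genes, LPS recognition and TLR4 signalling, acute-phase genes, homeostatic microglia, disease-associated microglia, and reactive astrocytes of the pan-reactive, LPS-type (A1) and ischaemia-type (A2) kinds. Others covered MHC class I presentation, MHC class II presentation, complement, endothelial activation, endothelial identity and barrier, cholesterol biosynthesis, LXR targets and lipid efflux, endocytosis and endosomal trafficking, the lysosome, mouse counterparts of Alzheimer risk genes, immediate early genes, glucocorticoid-responsive genes, heat shock and chaperones, the circadian clock, mitochondrially encoded genes, and extracellular matrix and collagens. The marker lists were of neurons, astrocytes, oligodendrocytes, their precursors, pericytes and smooth muscle, meningeal fibroblasts, choroid plexus, ependyma, erythrocytes, neutrophils, monocytes, lymphocytes, striatum, thalamus and hippocampus. Members were tested in 39 lists; of the mitochondrially encoded genes none had a count, so that list had no result. Lists were tested with camera of limma 3.58.1 on voom values with the preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry. The adjustment was over the lists of a contrast. Camera compares a list with all other genes, whereas fry asks whether the members of a list move one way on balance. The members past the threshold were counted with the adjustment over all genes and again adjusted over the list alone.

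Named genes follow a rule that was fixed before the data were examined. It takes Abca7; in a contrast with at most 30 genes past the threshold all of them, and otherwise the 8 with the largest increase and the 8 with the largest decrease among genes past the threshold with an average log2 CPM of at least 1 and no overlap between the libraries of the groups compared; up to 4 members with the smallest p of each list described, plus members against the direction of the list; Cd14, Tlr4, Tnf, Il1b, Il6, Trem2, Cd68, Aif1, Apoe and Abca1 in every contrast; genes of a check of sex; and the 5 genes with the smallest p where none passed. In the LPS effects, 1522 and 925 genes in control and labelled Abca7 mice were eligible for the part on the largest changes. The choroid plexus gene Ttr and the genes named for chromosome 10, among the surplus genes of other settings and in the last part of the text outside these rules were chosen after their values were seen. Some genes that the rule takes are not reported here.

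The fits were tested on simulated data before use. Counts were drawn from the gene means of the unstimulated control libraries, used for all 4 groups, and the library sizes of all libraries. In each contrast 200 genes were changed by known factors, and the members of a further list were raised 1.3-fold. Genes varied independently and nothing else differed between groups. The rates below therefore do not cover outlying libraries or shifts that many genes share. In the LPS effect in control mice, edgeR recovered 52% of genes changed 1.2-fold, 92% at 1.5-fold and 100% at 2-fold, over 21382 genes with 3.59% of the calls false. In the genotype effect without LPS, it recovered 42%, 98% and 98% over 21373 genes, with 4.17% false; in the genotype effect under LPS 62%, 90% and 98% over 21397 genes, with 3.02% false; and in the interaction 36%, 80% and 94% over 21399 genes, with 5.20% false. In the LPS effect in mice labelled Abca7, it recovered 56%, 92% and 96% over 21377 genes, with 3.57% false. DESeq2 gave between 8.53% and 12.4% false calls in the same simulations. For 50 lists without a planted change, camera gave 0 to 2 with p under 0.05 and fry 2 to 4. These lists were of random genes drawn independently, so they do not show how camera does where the members of a list are correlated.

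The alternatives were other scaling factors (median of ratios and upper quartile), DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of CPM of at least 1 in at least 6 libraries, a fit of only the groups compared, age as a number and as a factor, groups of animals with the same age and neighbouring numbers as a random effect (10 clusters), Xist level as a covariate, 5 surrogate variables from sva 3.50.0, and leaving out each library in turn. Chosen after seeing the data were the Ttr level and the share of counts in Yam1 and AY036118 as covariates, fits without labelled Abca7 LPS replicate 4 or without 3 libraries that stood apart (that library, control LPS replicate 4 and unstimulated labelled Abca7 replicate 1), and the genotype effect averaged over both stimuli. To see how often an arbitrary grouping gives as many calls, each contrast was refitted for 100 splits of its libraries, the real one included. Age in days is the only batch the labels give. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

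Total counts ran from 48149131 to 75741388 per library, so that counting error is small beside the spread between mice for all but the rarest transcripts. Intervals for counts near 0 cover counting error only. Within groups, 60 pairs of libraries were compared for duplicates by the chi-square of their counts per degree of freedom, which was between 5.12 and 44.4, so no pair was a library deposited again.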

Results

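Cortical RNA of 24 mice was compared across 4 groups of 6, formed by the genotype label (control or Abca7) and the stimulus label (none or LPS). The mice were 54 to 58 days old, and the groups were not matched for age: the LPS groups were 54 to 56 days old and the unstimulated groups 55 to 58. Total counts averaged 59698900 ± 5782080 (SD, n = 6) in unstimulated control libraries, 61832500 ± 8066220 in control LPS libraries, 55162400 ± 4883570 in unstimulated libraries labelled Abca7 and 58720407 ± 10170800 in LPS libraries labelled Abca7. These totals did not differ between the groups compared by more than the spread between libraries (exact permutation p = 0.617 and 0.496 for LPS, 0.171 and 0.550 for genotype, n = 6 per group). The first principal component held 44.0% of the variance and separated the stimuli, with means of -38.6 ± 5.58 and -36.4 ± 4.10 without LPS and 42.3 ± 4.41 and 32.7 ± 12.8 under LPS in control and labelled Abca7 mice. Its lowest LPS score was 9.87, in labelled Abca7 LPS replicate 4. All libraries had the pattern of males, with 5 to 44 counts of Xist, which is transcribed from the inactive X chromosome, and 2729 to 4871 counts of the Y-linked gene Ddx3y.

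A pair of loci inside the ribosomal RNA repeat on chromosome 17, Yam1 (17:39846958-39848788) and AY036118, took between 5.88% and 18.7% of the counts of a library. The share did not differ between groups by more than the spread (exact permutation p = 0.911 and 0.790 for LPS, 0.985 and 0.807 for genotype, n = 6 per group). All 37 genes of the mitochondrial chromosome had 0 counts in every library, while nuclear pseudogenes of mitochondrial genes, such as Gm13340 on chromosome 2, each held up to 0.522% of the counts. Mitochondrial transcripts were therefore not measured.

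Abca7 encodes a lipid transporter of the ATP-binding cassette family, and its mouse gene (ENSMUSG00000035722, 10:79996494-80015572, protein-coding) was read in every library with 1111 to 2312 counts. Its level was not lower in the mice labelled Abca7. Without LPS it averaged 32.1 ± 2.07 CPM (SD, n = 6) in these mice and 28.6 ± 2.22 CPM in controls, a log2 difference of 0.17 ± 0.07 (SE; adjusted p = 0.606; exact permutation p = 0.0238). Under LPS it averaged 29.4 ± 2.30 CPM against 24.5 ± 2.66 CPM, a log2 difference of 0.26 ± 0.07 (adjusted p = 0.267; exact permutation p = 0.00866). DESeq2 called the difference under LPS (adjusted p = 0.0490). Within 1 age the direction was the same, with log2 CPM of 5.02 in 3 unstimulated mice labelled Abca7 and 4.81 in 2 controls at 55 days, and 4.92 against 4.73 in 2 and 3 LPS mice at 56 days. Counts per gene include reads from any part of the transcript, so they cannot check the loss of a few exons on 1 chromosome. The mice are called "labelled Abca7" throughout, and each genotype difference is a difference between labels. LPS lowered Abca7 in control mice (log2 fold change -0.22 ± 0.07, adjusted p = 0.0189) and the change in mice labelled Abca7 was -0.13 ± 0.07 (adjusted p = 0.242), with no call for the difference between them (interaction 0.09 ± 0.09, adjusted p = 1). The call in control mice ended without control LPS replicate 1 (adjusted p = 0.0510), control LPS replicate 3 (0.0604) or unstimulated control replicate 4 (0.0629), and with Ttr level (0.181) or surrogate variables (0.591) in the model.

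**Figure D1:**
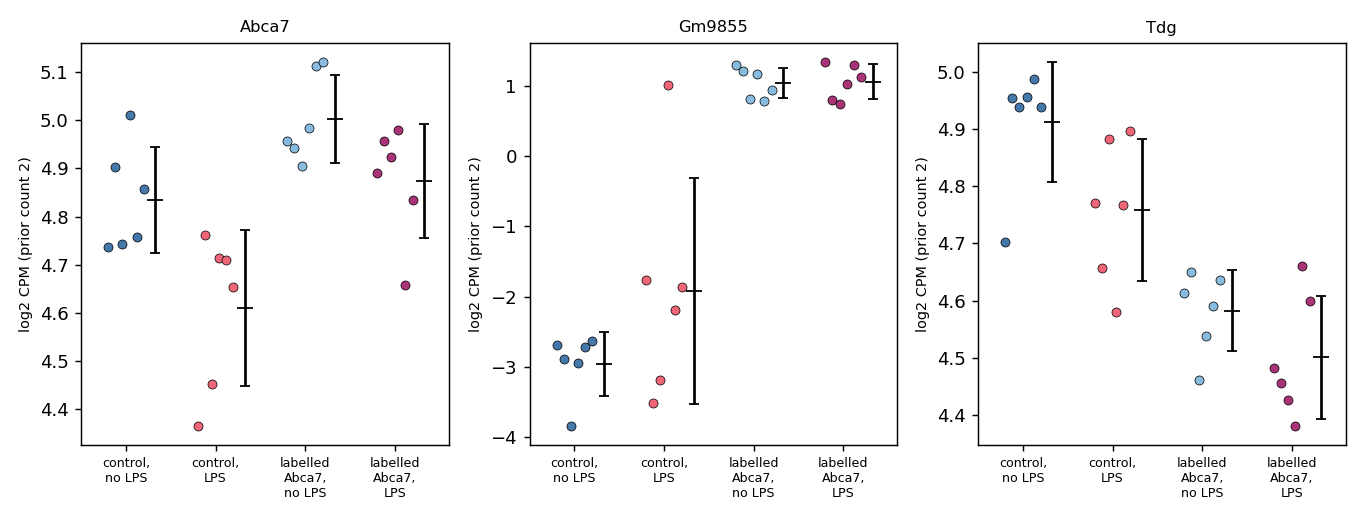
Log2 CPM (prior count 2) of Abca7, Gm9855 and Tdg in each of the 24 libraries, by group; points are libraries, and bars beside them show the mean and SD of 6. Abca7 is not lower in the groups labelled Abca7, whereas Gm9855 lies between 0.73 and 1.34 there and at -1.77 or below in all control libraries but control LPS replicate 4 (1.01).

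The first comparison asked what LPS does to the cortex of control mice. Of 1522 genes past the threshold with an average log2 CPM of at least 1 and no overlap between the libraries of the 2 groups, 860 rose and 662 fell. Of these, the neutrophil attractant Cxcl2 (5:90903899-90905909) rose the most, by 9.49 ± 0.72 on the log2 scale (SE, n = 6 per group; adjusted p = 4.9e-11), and the T cell attractant Cxcl10 (5:92346638-92348889) by 8.71 ± 0.45, from 0.47 ± 0.21 to 195 ± 38.2 CPM. The siderophore-binding protein gene Lcn2 (2:32384633-32388252) rose by 8.37 ± 0.30. Saa3 (9.05 ± 0.57), Ccl2 (8.76 ± 0.62), Cxcl9 (8.72 ± 0.63), Cxcl1 (8.66 ± 0.64) and the endothelial adhesion gene Selp (8.35 ± 0.54) completed the 8 largest increases of this set, which leaves out rarer transcripts such as Tnf. The largest decreases of the set were in the endothelial transcription factor genes Sox17 (1:4490931-4497354; -3.06 ± 0.16, from 5.84 to 0.693 CPM) and Sox18 (-2.84 ± 0.20), in the blood-brain barrier transporter gene Slco1a4 (-2.23 ± 0.16, from 52.8 to 11.2 CPM) and in Hspa12b (-2.18 ± 0.14). Tek, an angiopoietin receptor gene of endothelium, fell by 1.86 ± 0.09, the microglial genes Gpr34 and Cx3cr1 by 2.12 ± 0.19 and 1.77 ± 0.12, and the immediate early gene Egr2 by 1.93 ± 0.25. Ccl2, Cxcl10, Selp, Sox17, Hspa12b, Gpr34 and Cx3cr1 overlap other annotated genes, from which their counts cannot be separated without strand.

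With edgeR, 3790 of 21891 genes passed the threshold in control mice, 2056 higher and 1734 lower (54.2% higher), and 781 changed more than 2-fold, 627 up and 154 down. At an unadjusted p under 0.05 there were 6364. The count fell to 1836 with surrogate variables and to 1626 with the Ttr level as a covariate; Ttr is a choroid plexus gene whose level differed between these groups, with a mean of 284 ± 109 CPM under LPS and 53.1 ± 102 CPM without. With age as a factor 3853 genes passed. Both of the first 2 models ended the calls of Aif1, Trem2, Plac8, Clcf1, Mfsd2a, Ier2, Folr1 and Tcf7l2; surrogate variables alone also ended that of Btg2 (adjusted p = 0.0906), and the Ttr level alone those of Kl (0.929) and Vwf (0.144). Baseline levels of several induced genes were close to 0, and the 6 unstimulated control libraries held 1 count of Tnf in all against 752 under LPS, a ratio of 721 with a counting interval of 129 to 28521.

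Every measured gene of the proinflammatory list rose, 23 of 23 with a median log2 fold change of 5.52, among them Ccl12 (5.58) and the adhesion gene Icam1 (5.20). The list call was lost when the correlation between genes was estimated (adjusted p = 0.0658 with an estimated correlation). Within mice of 55 days the mean log2 CPM of this list was -1.31 in 2 unstimulated and 3.65 in 2 LPS mice, and within those of 56 days -1.20 and 3.51 in 3 and 3. Of the interferon-stimulated genes, 31 of 31 rose (median 3.49, adjusted p = 0.00564 with an estimated correlation), with Trim30a at 3.70 ± 0.13, Irf7 at 4.10 ± 0.17 and Rsad2 at 7.57 ± 0.33; their mean was 1.18 and 4.76 at 55 days and 1.43 and 4.75 at 56 days. All 17 acute-phase genes rose (median 3.88, 0.00676 with an estimated correlation), such as Serpina3f (8.34 ± 0.26) and Socs3 (3.88), and so did all 15 genes of MHC class I presentation (median 1.69, 0.00676), such as Tap1 (3.37) and Nlrc5 (4.29). Adjusted over the list alone, these counts were the same. In the list of LPS recognition and TLR4 signalling, 11 of 20 genes rose, 12 adjusted over the list alone (median 0.25, 0.0115 with an estimated correlation). Tlr2 (4.73), Map3k8 (2.29) and Myd88 (1.58) were among them, as was the LPS co-receptor gene Cd14, which rose by 3.94 ± 0.24, whereas the LPS receptor gene Tlr4 did not pass (0.12 ± 0.17, adjusted p = 0.694). Of the cytokine genes, Il1b rose by 4.61 ± 0.46 and Il6 by 6.89 ± 0.62. In the complement list 10 of 15 genes rose, 12 up and 1 down adjusted over the list alone (median 0.54, 0.0166 with an estimated correlation); C5ar1 (3.45) and C1ra (1.49) are examples, and C1ra shares 50.8% of its 50-base sequences with other genes, mostly C1rb.

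Microglial genes divided by list. Of 20 homeostatic microglia genes 14 fell and 2 rose, 14 and 3 adjusted over the list alone (median -0.42, adjusted p = 0.00676 with an estimated correlation). The purinergic receptor gene P2ry12 fell by 1.43 and Tmem119 by 1.17, while C1qb (0.41) and Fcrls (0.26) rose; the microglial receptor gene Trem2 fell by 0.41 ± 0.09 (adjusted p = 0.00158) and Aif1 by 0.39 ± 0.10 (adjusted p = 0.00592). Both calls ended with the Ttr level in the model (adjusted p = 0.0973 for Trem2 and 0.125 for Aif1). Of 20 disease-associated microglia genes 9 rose, 10 adjusted over the list alone (median 0.14), including Csf1 (1.29) and B2m (0.77), a call lost otherwise (adjusted p = 0.0658 with an estimated correlation). Cd68 (-0.03 ± 0.08, adjusted p = 0.841) and Apoe (0.03 ± 0.05, adjusted p = 0.733) did not pass. Abca1, a cholesterol efflux transporter gene related to Abca7, rose by 0.53 ± 0.06 (adjusted p = 4.34e-07). Of the 8 monocyte markers 5 rose (median 0.31, 0.0166 with an estimated correlation), led by Ms4a4c (4.03) and Plac8 (2.94).

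Astrocyte reactivity genes rose in all 3 sets. The pan-reactive set had 12 of 13 members higher (median 2.20, 0.0220 with an estimated correlation), with Osmr at 3.02 and Cp at 2.20, and Vim at -0.02 was the member that did not pass. The A1 set had 10 of 12 higher (median 1.02, 0.00564), with Iigp1 at 6.02 and Gbp2 at 5.90. The A2 set had 9 of 12 higher (median 1.63, 0.0325), with Slc10a6 at 4.20 and Tgm1 at 2.64, while Clcf1 fell by 0.61, a call lost without control LPS replicate 3 (adjusted p = 0.0522). Adjusted over the list alone, the counts of the 3 sets were the same. Of 12 general astrocyte markers 3 rose, 4 adjusted over the list alone (median 0.08, adjusted p = 0.389 with an estimated correlation), with Aldh1l1 at 0.27.

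Blood vessel genes moved in opposite directions by list. Of 16 endothelial activation genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone (median 1.57, adjusted p = 0.0124 with an estimated correlation), with Ch25h at 5.18 and Vcam1 at 1.71, and Vwf, the gene of von Willebrand factor, fell by 0.89. Of 17 endothelial identity and barrier genes 11 fell and 3 rose, the same adjusted over the list alone (median -0.75, 0.00676). The vascular endothelial cadherin gene Cdh5 (1.41), Ly6a (1.33) and Mfsd2a (0.30) were the 3 that rose. The call of Mfsd2a was lost without control LPS replicates 3, 4 or 5 or unstimulated control replicates 1, 2 or 3 (adjusted p 0.0506 to 0.0754). Of 10 meningeal fibroblast genes 5 fell, also adjusted over the list alone (median -0.32, adjusted p = 0.160 with an estimated correlation), led by Slc22a6 (-1.53).

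Among immediate early genes 12 of 18 fell and 2 rose, the same adjusted over the list alone (median -0.49, adjusted p = 0.160 with an estimated correlation), with Egr4 at -1.27 and Nr4a3 at -1.35. Btg2 (0.67) and Ier2 (0.49) rose; the call of Ier2 was lost without control LPS replicates 1 or 3 or unstimulated control replicates 2, 3, 5 or 6 (adjusted p 0.0543 to 0.0690). Glucocorticoid-responsive genes rose in 14 of 18 cases and 1 fell, 15 and 1 adjusted over the list alone (median 0.46, 0.0166 with an estimated correlation); the metallothionein gene Mt2, which shares 45.9% of its 50-base sequences with another gene, rose by 1.84 and the clock gene Per1 fell by 0.60. Of 15 circadian clock genes 5 fell, also adjusted over the list alone (median -0.06, adjusted p = 0.133 with an estimated correlation), such as Per2 (-0.81). Of 10 choroid plexus markers 7 rose, 9 adjusted over the list alone (median 1.25, adjusted p = 0.304 with an estimated correlation), such as Kl (1.70 ± 0.37) and Folr1 (1.77), whereas with the Ttr level in the model their values were -0.051 and -0.22. Of 8 thalamus markers 1 rose, Tcf7l2 (1.202), and 2 adjusted over the list alone (median 0.64, adjusted p = 0.585 with an estimated correlation); its call was lost with DESeq2 (0.0537) and without any 1 of 9 libraries, control LPS replicates 2 to 5 and unstimulated control replicates 2 to 6 (adjusted p 0.0634 to 0.113). Over all 39 lists, camera called 21, 16 higher and 5 lower, of which 13 held with an estimated correlation, and fry called 21, 20 of them the same. The 18 other lists were not called by camera, with adjusted p from 0.101 for ependyma to 0.852 for hippocampus: neurons, pericytes and smooth muscle, striatum, oligodendrocytes and their precursors, LXR targets, erythrocytes, neutrophils, cholesterol biosynthesis, heat shock, Alzheimer risk counterparts, lymphocytes, MHC class II, lysosome, extracellular matrix and endocytosis lay between them. Fry called 1 of these, the neutrophil list, as higher (adjusted p = 0.0452).

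The second comparison asked what LPS does in mice labelled Abca7. Cxcl11 rose by 7.99 ± 0.54 (SE, n = 6 per group), Serpina3f (12:104214544-104221129) by 7.66 ± 0.26 (adjusted p = 3.29e-17), Cxcl10 by 7.29 ± 0.41, from 1.09 ± 0.73 to 165 ± 73.9 CPM, and the interleukin 1 receptor antagonist gene Il1rn by 7.27 ± 0.64. Saa3 (6.98 ± 0.51), Slfn4 (6.96 ± 0.38), Selp (6.86 ± 0.50) and Ccl2 (6.83 ± 0.54) followed. Among the genes that met the same conditions, the largest decreases were those of Sox17 (-2.71 ± 0.16, from 5.64 to 0.875 CPM), Sox18 (-2.65 ± 0.20), Hspa12b (-2.05 ± 0.13), Fmo2 (-1.88 ± 0.29), Slco1a4 (-1.88 ± 0.16), the tight junction gene Cldn5 (-1.78 ± 0.17), Egr2 (-1.72 ± 0.25) and Gpr34 (-1.65 ± 0.18). Il1b rose by 4.82, Il6 by 5.46, Tnf by 7.01, Cd14 by 3.79 and Abca1 by 0.32, while Aif1 and Trem2 fell by 0.42 and 0.32. Tlr4 (-0.06), Apoe (-0.01) and Cd68 (-0.10) did not pass. Of the genes named, Cxcl11 shares 40.4% of its 50-base sequences with another gene and overlaps Art3, as does Cxcl10.

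With edgeR, 2591 genes passed in these mice, 1456 higher and 1135 lower (56.2% higher); 631 changed more than 2-fold, 507 up and 124 down, and 5141 had an unadjusted p under 0.05. The count fell to 1270 with surrogate variables, which ended the calls of Trem2 (adjusted p = 0.381), Abca1 (0.120), Aif1 (0.0546), C1qa (0.0936), Tyrobp (0.0968) and Fcrls (0.147). With age as a factor 2350 genes passed, and the calls of Tyrobp (0.129) and Fcrls (0.165) ended. The spread within the labelled Abca7 LPS group was wide for induced genes because replicate 4 lay apart; the mean of the proinflammatory list in it was 1.07 log2 CPM against 2.96 to 3.97 in the other 5.

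Again 23 of 23 proinflammatory genes rose (median 4.86, adjusted p = 0.0541 with an estimated correlation), and the mean of the list at 55 days was -0.94 in 3 unstimulated and 3.46 in 2 LPS mice. Interferon-stimulated genes rose in 30 of 31 cases (median 3.23, 0.00397 with an estimated correlation), such as Trim30a (3.47) and Rsad2 (6.63), with a mean of 1.33 and 4.67 at 55 days; acute-phase genes in 17 of 17 (median 3.50, 0.00438), such as Lcn2 (6.80); and MHC class I genes in 14 of 15 (median 1.41, 0.00548), such as Nlrc5 (3.31). Adjusted over the list alone the counts were 23, 30, 17 and 15. LPS recognition genes rose in 8 of 20 cases (median 0.14, 0.0171), also adjusted over the list alone, and complement genes in 9 of 15 with 1 lower (median 0.34, 0.0458), 11 and 1 adjusted over the list alone. The pan-reactive astrocyte set had 11 of 13 members higher (median 1.82, 0.0299), 12 adjusted over the list alone; the A1 set 8 of 12 (median 0.81, 0.00538), 10 and 1 lower adjusted over the list alone; and the A2 set 7 of 12 (median 1.14, adjusted p = 0.0541 with an estimated correlation), 8 and 1 lower.

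Homeostatic microglia genes fell in 14 of 20 cases and 4 rose, also adjusted over the list alone (median -0.37, 0.00890 with an estimated correlation). Cx3cr1 fell by 1.45, P2ry12 by 1.19 and Tmem119 by 0.83, while the complement genes C1qa (0.25) and C1qb (0.34), Tyrobp (0.26) and Fcrls (0.18) rose. The call of Tyrobp was lost without unstimulated replicate 1 (adjusted p = 0.0591) or LPS replicate 5 (0.0554), and that of Fcrls without unstimulated replicates 3 to 6 or LPS replicates 1, 3, 5 or 6 (0.0530 to 0.110). Disease-associated microglia genes rose in 4 of 20 cases (median 0.11, adjusted p = 0.260 with an estimated correlation) and monocyte markers in 3 of 8 (median 0.18, 0.0490), 4 in both lists adjusted over the list alone. Endothelial activation genes rose in 13 of 16 cases with Vwf lower by 0.95 (median 1.28, 0.0171), 14 and 1 adjusted over the list alone; endothelial identity genes fell in 11 of 17 and 2 rose, Ly6a (1.05) and Cdh5 (1.13), also adjusted over the list alone (median -0.62, 0.00397). The angiopoietin receptor gene Tek fell by 1.55 and the tight junction gene Ocln by 1.17. Meningeal fibroblast genes fell in 6 of 10 cases (median -0.54, 0.0458), 7 adjusted over the list alone, such as Slc6a13 (-0.94) and Ogn (-1.18).

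Immediate early genes fell in 12 of 18 cases and 0 rose, 14 adjusted over the list alone (median -0.48, adjusted p = 0.0909 with an estimated correlation), such as Nr4a1 (-1.13). Glucocorticoid-responsive genes rose in 14 of 18 with Per1 lower by 0.43 (median 0.43, 0.0227), 15 and 2 adjusted over the list alone. Further calls were lost with an estimated correlation: circadian clock (3 lower, median -0.05, adjusted p = 0.171 with an estimated correlation), pericytes and smooth muscle (3 lower, -0.13, 0.230), heat shock (3 lower, -0.07, 0.622), cholesterol biosynthesis (4 higher, 0.07, 0.648), thalamus (0 past the threshold, 0.57, 0.589) and striatum (0, -0.13, 0.621). Adjusted over the list alone, 3, 4, 6, 5, 0 and 0 members passed in that direction. The choroid plexus list was not called (0 members, median -0.37, adjusted p = 0.156). Camera called 23 lists, 15 higher and 8 lower, of which 13 held with an estimated correlation, and fry called 20, of which 19 were the same and the other was the neutrophil list (adjusted p = 0.0150). The lists not called by camera had adjusted p from 0.156 to 0.923. Where 1 list had a median, a mean and a test that differed in sign (25 of 195 tests over all contrasts), it was not called by camera.

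The LPS effects of the 2 genotype labels ran together among the genes called. Of these, 2143 were called under both labels and all of them changed in the same direction, 1245 up and 898 down, where independent lists would share 137 and 89.9; no library was common to these contrasts. Across 21891 genes the log2 fold changes had a Pearson correlation of 0.89 and a Spearman correlation of 0.62, whereas the Pearson correlation was 0.303 across 34641 genes without the filter, where genes with few counts enter. Across the 4238 genes called under either label the Pearson correlation was 0.96 and 97.2% had the same sign. Genes are not independent replicates, so no p is given. A further 1647 genes were called in control mice only and 448 in mice labelled Abca7 only, but the interaction test, which tests the difference itself, called 0 genes.

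**Figure D2:**
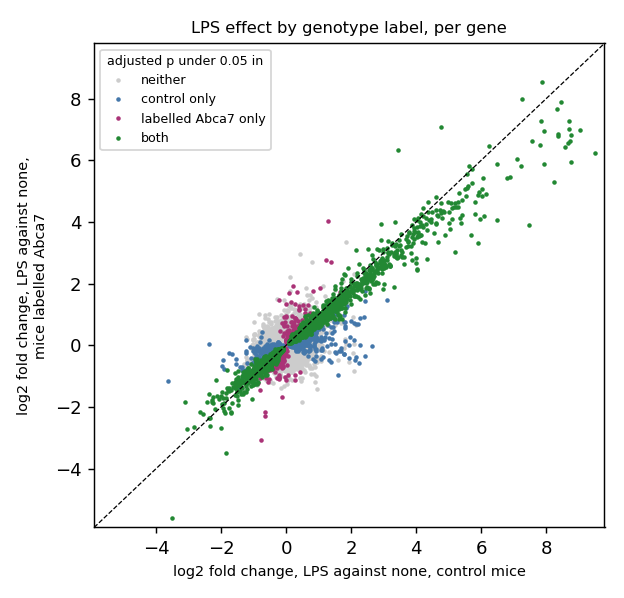
Log2 fold change of each of 21891 genes, LPS against none, in control mice (horizontal) and in mice labelled Abca7 (vertical); colour gives the label or labels under which the gene had an adjusted p under 0.05, and the dashed line marks equal effects. The 2143 genes called under both labels have the same sign on both axes.

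The third comparison asked how the genotype labels differ without LPS. Differences were few, and 3 of the 7 genes past the threshold lie on chromosome 10. The pseudogene Gm9855 (ENSMUSG00000085666, 10:42054113-42055306) was higher in mice labelled Abca7 by 4.31 ± 0.57 (SE, n = 6 per group; adjusted p = 0.00118), 2.04 ± 0.31 against 0.10 ± 0.03 CPM. The DNA repair gene Tdg (ENSMUSG00000034674, 10:82629828-82650799), a thymine DNA glycosylase, was lower by 0.33 ± 0.06 (adjusted p = 0.0173), 23.9 ± 1.16 against 30.2 ± 2.08 CPM, and the neighbouring 1190007I07Rik (10:82619851-82623228) had a log2 difference of -0.64 ± 0.10 (adjusted p = 0.00991). On other chromosomes, Ccdc108 (1:74902071-74935599) was higher by 0.45 ± 0.08 (adjusted p = 0.0173) and Dlec1 (9:119102478-119148246) by 0.42 ± 0.07 (adjusted p = 0.0208), while Plcxd2 (16:45959263-46010218) was lower with -0.24 ± 0.04 (adjusted p = 0.0173), and so was the potassium channel gene Kcnh5 (12:74897217-75177332) with -0.28 ± 0.05 (adjusted p = 0.0428). Gm9855 shares 85.3% of its 50-base sequences with other genes, 76.5% with Tdg, and the assignment of reads between them is not known. Ccdc108, Plcxd2, Tdg and Dlec1 overlap other annotated genes. At 55 days, Gm9855 averaged 1.11 log2 CPM in 3 mice labelled Abca7 and -2.67 in 2 controls, and Tdg 4.61 and 4.96; at 56 days the values were 0.81 (1 mouse) and -3.14 (3 mice), and 4.46 and 4.86.

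With edgeR, 7 genes passed without LPS, 3 higher and 4 lower, and 1426 had an unadjusted p under 0.05; DESeq2 called 31 and limma-voom 6. The count went from 2 to 38 when single libraries were left out. It was 38 without unstimulated control replicate 1 and 19 without unstimulated labelled Abca7 replicate 1; it was 2 without control replicates 4 or 6 or labelled Abca7 replicates 3 or 4, 3 without control replicate 3, and 4 without control replicates 2 or 5 or labelled Abca7 replicates 5 or 6. Gm9855 and 1190007I07Rik stayed past the threshold in each of these fits, whereas Tdg lost its call without control replicates 2 to 6 or labelled Abca7 replicates 3 to 5 (adjusted p 0.0506 to 0.0750), Ccdc108 without control replicates 3, 4 or 6 or labelled Abca7 replicates 3 or 4 (0.0502 to 0.0750), Plcxd2 without control replicates 4 to 6 or labelled Abca7 replicates 3 to 6 (0.0502 to 0.0834), Dlec1 without control replicates 2 to 6 or labelled Abca7 replicates 3, 4 or 6 (0.0515 to 0.108), and Kcnh5 without control replicates 2, 3, 4 or 6 or labelled Abca7 replicates 2 to 6 (0.0505 to 0.211). With the Ttr level in the model, Gm9855 was the only 1 of the 7 to keep its call; with the Xist level, Gm9855 and 1190007I07Rik kept theirs (adjusted p 0.0924 to 0.147 for the other 5), and with only the 2 groups compared in the fit these and Tdg did (0.0762 to 0.398 for the other 4). Dlec1 also lost its call without the filter (0.0639) and without the 3 libraries that stood apart (0.0580), and Kcnh5 with upper-quartile factors (0.0831), limma-voom (0.0583) and the stricter filter (0.0505).

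Of the lists, 4 were called by camera and 0 held with an estimated correlation (smallest adjusted p = 0.207); fry called 0. All 10 choroid plexus markers were higher in the mice labelled Abca7 (median 1.52, adjusted p = 0.207 with an estimated correlation), 0 past the threshold over all genes and 9 adjusted over the list alone. Sostdc1 (1.60 ± 0.38), Kl (1.53 ± 0.37), Kcnj13 (1.23 ± 0.28; 42.1% of its 50-base sequences shared) and Clic6 (1.09 ± 0.27) are examples. These 4 became past the threshold without unstimulated control replicate 1 (adjusted p 0.00480 to 0.0194) or unstimulated labelled Abca7 replicate 1 (0.0203 to 0.0429). Ttr, the transthyretin gene and the most abundant marker, was at 8.03 log2 CPM in control replicate 1 and at 2.31 to 4.30 in the other 5 controls, and at 5.59 in labelled Abca7 replicate 1 and 7.47 to 8.81 in the other 5 of that group. At 55 days it averaged 8.29 in 3 mice labelled Abca7 and 3.11 in 2 controls. All 8 ependymal markers were also higher (median 0.29, adjusted p = 0.856 with an estimated correlation), with Rsph1 at 0.42 ± 0.16. The cholesterol biosynthesis list was lower (median -0.05, 20 of 22 members negative; 0.856 with an estimated correlation), with Insig1 at -0.17, as was the endocytosis list (median -0.03, 23 of 30 negative; 0.856), with the sorting receptor gene Sorl1 at -0.12 ± 0.04. In the last 3 lists 0 members passed over all genes or adjusted over the list alone. Cd14, Tlr4, Tnf, Il1b, Il6, Trem2, Cd68, Aif1, Apoe and Abca1 did not pass (adjusted p 0.942 for Aif1 to 1 for Trem2).

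**Figure D3:**
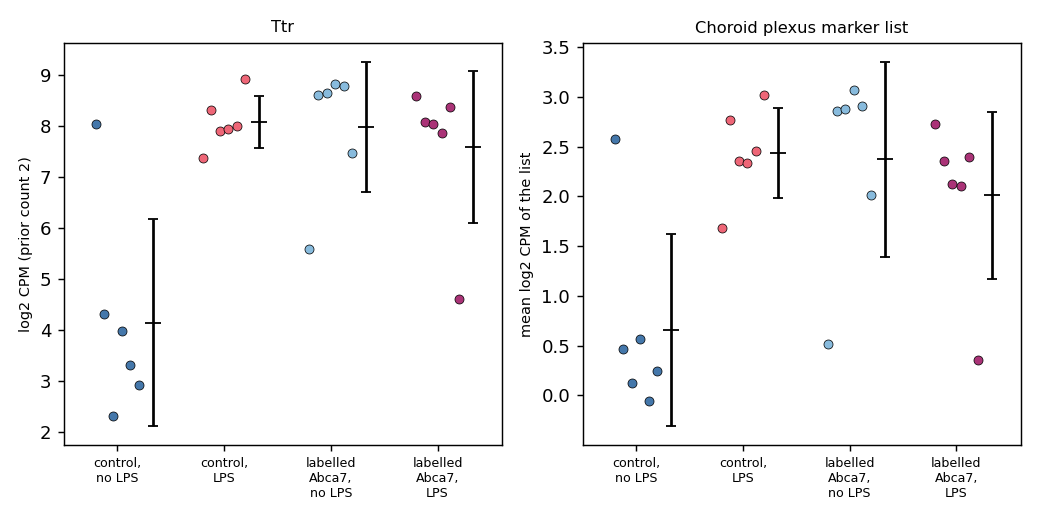
Log2 CPM of Ttr (prior count 2) and mean log2 CPM of the 10 choroid plexus markers in each of the 24 libraries, by group; points are libraries, and bars beside them show the mean and SD of 6. In unstimulated controls, 5 of 6 libraries lie at or below 4.30 for Ttr and replicate 1 lies at 8.03.

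The fourth comparison asked how the genotype labels differ under LPS. No gene passed. Inflammatory gene groups had lower values in the LPS libraries labelled Abca7 than in control LPS libraries, with list medians from -0.08 to -0.31 on the log2 scale. None of these lists held with an estimated correlation (smallest adjusted p = 0.353), fry called 0 lists, and 0 members passed over all genes. The genes with the smallest p did not pass (adjusted p = 0.267 for each): Gm15283 (-0.25 ± 0.05), Foxp3 (0.26 ± 0.05), RP24-426M1.3 (-0.22 ± 0.05), Gm9855 (2.07 ± 0.45) and Tenm3 (-0.17 ± 0.04). RP24-426M1.3 shares 88.5% of its 50-base sequences with other genes and Foxp3 23.1%. Abca1 had -0.27 ± 0.06 (adjusted p = 0.267), 61.0 ± 4.83 against 73.6 ± 5.31 CPM. For Cd14 (-0.30 ± 0.20), Tlr4 (-0.25 ± 0.17), Il6 (-0.50 ± 0.35), Il1b (-0.20 ± 0.34), Tnf (-0.16 ± 0.28), Trem2 (0.07 ± 0.09), Aif1 (0.09 ± 0.10), Cd68 (0.02 ± 0.08) and Apoe (0.00 ± 0.05) the difference was below 2 SE.

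With edgeR, 0 genes passed and 1748 had an unadjusted p under 0.05; DESeq2 called 37 and limma-voom 1. Control LPS replicate 4 had a Gm9855 level of 1.01 log2 CPM, inside the range of the mice labelled Abca7, and without it 1 gene passed, Gm9855 (3.67, adjusted p = 1.97e-09). At 55 days Gm9855 averaged 1.21 in mice labelled Abca7 and -1.82 in controls under LPS (2 and 2 mice).

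Camera called 15 lists under LPS, 1 higher and 14 lower; with an estimated correlation 0 held (smallest adjusted p = 0.353), and fry called 0. In the interferon-stimulated list 30 of 31 members were negative (median -0.18, adjusted p = 0.353 with an estimated correlation), such as Ifih1 (-0.25), and in the proinflammatory list 23 of 23 (median -0.24, 0.432), such as Ptgs2 (-0.32 ± 0.18). The acute-phase list had 15 of 17 negative (median -0.30, 0.353), such as Serpina3n (-0.47). Lower medians with an adjusted p of 0.353 with an estimated correlation were found for A2 (-0.31) and pan-reactive (-0.24) astrocytes, endothelial activation (-0.18), A1 astrocytes (-0.18), complement (-0.18), LPS recognition (-0.13), disease-associated microglia (-0.08) and endocytosis (-0.03); MHC class I (-0.17) and LXR targets (-0.05) had 0.432, and the choroid plexus list (-0.35) had 0.704. The homeostatic microglia list was higher (median 0.08, 0.353), with Tmem119 at 0.37 ± 0.10. No member passed over all genes; adjusted over the list alone, 2 passed in the A2 list, 2 in the LXR list (Abca1 and Abca5, the second at -0.12 ± 0.03), and 1 each in the disease-associated microglia, endocytosis (Cltc, -0.11 ± 0.03) and homeostatic microglia (Tmem119) lists.

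The size of these list differences depended on which libraries entered. Without labelled Abca7 LPS replicate 4, camera called 9 lists, all lower, of which 7 were among the 15. The proinflammatory median went from -0.24 to -0.05 (adjusted p = 0.152), the acute-phase median to -0.17 (0.0195) and the interferon-stimulated median to -0.11 (0.00706). With control LPS replicate 4 and unstimulated labelled Abca7 replicate 1 left out as well, camera called 13 lists, 12 of them among the 15, and the 3 medians were -0.14 (adjusted p = 0.0000149), -0.16 (0.00210) and -0.15 (1.18e-08). These adjusted p are from camera with the preset correlation between genes. Control LPS replicate 4 had the lowest proinflammatory (3.11) and interferon-stimulated (4.59) list means of its group, but not the lowest acute-phase mean (3.05). Leaving it out raises the control means of the first 2 lists. The calls that return in that fit therefore do not show a difference free of outlying libraries. Tested over mice (n = 6 per group), the list mean differed by -0.20 for interferon-stimulated genes (exact permutation p = 0.141). For acute-phase genes it differed by -0.33 (exact permutation p = 0.171). The proinflammatory list mean was 3.12 ± 1.06 log2 CPM (SD, n = 6) in the LPS libraries labelled Abca7 and 3.63 ± 0.32 in control LPS libraries. That is a difference of -0.51 (exact permutation p = 0.314), and of -0.10 without labelled Abca7 LPS replicate 4 (exact permutation p = 0.643). At 55 days the means were 3.46 and 3.65 (2 and 2 mice), at 56 days 3.59 and 3.51 (2 and 3), and at 54 days 2.30 and 3.92 (2 and 1), with replicate 4 among the 54-day mice.

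**Figure D4:**
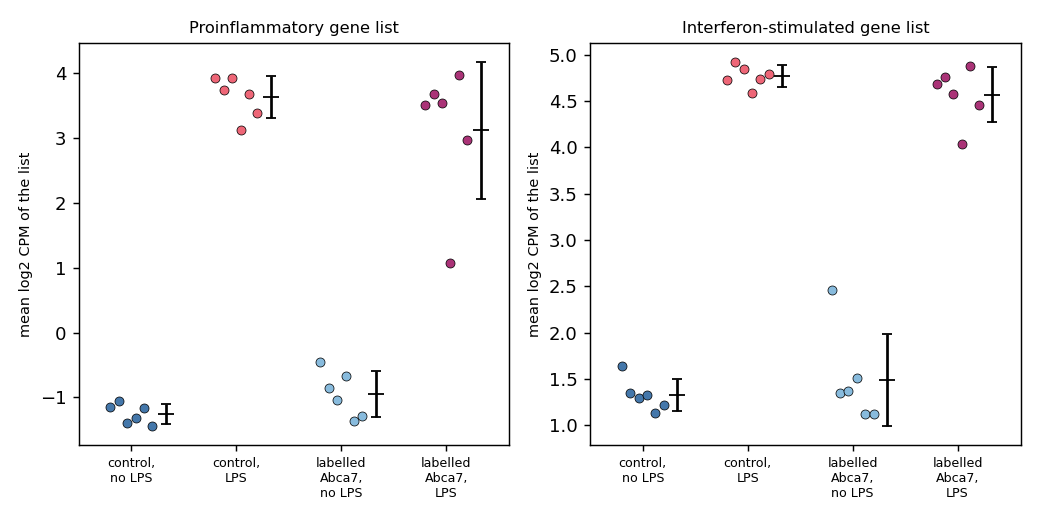
Mean log2 CPM of the proinflammatory list (left) and of the interferon-stimulated list (right) in each of the 24 libraries, by group; points are libraries, and bars beside them show the mean and SD of 6. Labelled Abca7 LPS replicate 4 lies at 1.07 in the left panel, below the other LPS libraries.

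The interaction asked whether the response to LPS differs by genotype label. With edgeR 0 genes passed, 745 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. The smallest p were those of Dlec1 (-0.48 ± 0.11), Sulf1 (-0.39 ± 0.09), the retinal transporter gene Abca4 (-0.87 ± 0.20), Wfdc2 (-2.55 ± 0.61) and Zfp710 (0.24 ± 0.06), with an adjusted p of 1 each. Dlec1 averaged 2.79 and 3.42 CPM in controls without and under LPS and 3.74 and 3.28 CPM in mice labelled Abca7. The choroid plexus list had the largest interaction among the lists, -1.91 with 10 of 10 markers negative (adjusted p = 0.0935 with an estimated correlation), 0 past the threshold over all genes and 9 adjusted over the list alone; Kl (-1.90) passed without unstimulated control replicate 1 (-2.43, adjusted p = 0.0354). Without LPS the median difference of the same markers between the labels was 1.52, with 0 past the threshold over all genes. Camera called 18 lists, 1 higher and 17 lower, including the interferon-stimulated (median -0.35, 31 of 31 negative; 0.435 with an estimated correlation), proinflammatory (-0.57; 0.599) and acute-phase (-0.48; 0.339) lists; with an estimated correlation 0 held and fry called 0. Without labelled Abca7 LPS replicate 4, 17 of the 18 kept the camera call and the proinflammatory median was -0.34 (adjusted p = 0.0195). With the 3 libraries that stood apart left out, 15 kept it, the proinflammatory median was -0.24 (0.00133), and the interferon-stimulated list, at -0.081, was not called (0.0757). The interaction also takes in the difference between the labels without LPS. There, list means were higher in mice labelled Abca7, by 0.31 for proinflammatory, 0.16 for interferon-stimulated and 0.23 for acute-phase genes. Their exact permutation p were 0.0823, 0.623 and 0.0368, and 0.458, 0.844 and 0.458 adjusted over the lists. Under LPS without labelled Abca7 LPS replicate 4 the proinflammatory median was -0.05, so the -0.34 lay largely in unstimulated mice. With the Ttr level in the model camera called 3 lists, 0 of them among the 18, and without unstimulated control replicate 1 the test called 7 genes. Cd14, Tlr4, Tnf, Il1b, Il6, Trem2, Cd68, Aif1, Apoe and Abca1 had an adjusted p of 1 each in the interaction.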

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

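The tests of choroid plexus tissue, of a genotype effect on its markers whatever the stimulus and of the share of ribosomal RNA counts were chosen after the values were seen, the criteria of several other tests were tightened then, and the remaining tests below were set before their results. The number of genes past the threshold was compared with other splits of the same libraries. For the LPS effect in control mice, 1 of 100 splits, the real one, gave 3790 genes or more, and the highest other split gave 1077; for mice labelled Abca7, 1 of 100 gave 2591 or more, and the highest other gave 1323. For the genotype effect without LPS, 1 of 100 gave 7 or more and the highest other gave 3. An arbitrary grouping is thus an unlikely source of the LPS counts, and of the 7 genes in the main fit only. With only the 2 groups compared in the fit, 3 genes passed without LPS, and no splits were drawn in that setting. For the genotype effect under LPS and for the interaction the real count was 0, which every split reaches (100 of 100), so these splits test nothing. The highest other splits gave 316 and 3 genes. Besides the real split, 92 splits under LPS gave 0 calls. The split with 316 points to some structure among these libraries, which no test here identified.

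Of 316 group values tested (48 genes, 29 list means, the total count and the share of ribosomal RNA counts, each in 4 groups of 6), 40 had 1 library far from the other 5, where chance alone gives about 1 in 20, or 15.8. Of the 40, 17 were in labelled Abca7 LPS replicate 4. There, the log2 CPM was -0.55 for Cxcl2, 0.83 for Ccl2, 5.11 for Cxcl10, 1.01 for Cxcl11, 4.85 for Lcn2, 0.61 for Selp, -1.23 for Il1b and 2.51 for Cd14, all below the other 5 LPS libraries of the label, and 2.17 for Gpr34 and 2.58 for Tek, both above them. The mean log2 CPM of lists there was 1.07 for proinflammatory, 1.63 for acute-phase, 3.40 for pan-reactive astrocyte, 1.26 for A2 astrocyte, 2.10 for complement, 2.25 for endothelial activation and 5.74 for glucocorticoid-responsive genes, all below the others. A shallow response of this mouse to LPS is a hypothesis for the lower inflammatory lists under LPS in mice labelled Abca7. Of the 13 pathway lists that were lower, 7 kept their call without this library (53.8%, exact 95% interval 25.1 to 80.8), and the mean of their medians went from -0.17 to -0.09. When control LPS replicate 4 and unstimulated labelled Abca7 replicate 1 were left out too, 11 kept it. That control library had the lowest proinflammatory list mean of its group (3.11), so leaving it out widens that difference. The unstimulated library is in neither group of this contrast. The interval counts the lists as independent, but they share members and libraries, so it does not measure the spread between mice. How far labelled Abca7 LPS replicate 4 accounts for the pattern cannot be told apart from a smaller difference between the labels. The proinflammatory list mean without it differed by -0.10 (exact permutation p = 0.643, n = 6 and 5), and a weaker response in the genotype as a whole stays open too, since 11 or 12 libraries are few for a difference of that size. A high share of ribosomal RNA counts in this library (16.5%) stays open as a source: control LPS replicate 1, at 16.2%, had a proinflammatory mean of 3.91, above the median of the rest, 3.60, but 1 library excludes nothing.

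A second pattern is on chromosome 10, where Abca7 lies: in the genotype effect averaged over both stimuli, 6 of 458 genes within 20 Mb of Abca7 passed (1.31%) against 51 of 21433 elsewhere (0.238%; Fisher's exact p = 0.00119), and without the 4 genes seen first 3 of 455 against 50 of 21432 (p = 0.0978). Of these 4, Gm9855 lies outside the 20 Mb window and was counted elsewhere, and Abca7 itself is among the 6. Linked variants of another strain around the altered gene may account for part of the genotype calls, and whether they do stays open. Reads moving from Tdg to its pseudogene Gm9855 with no change in their sum are argued against as the whole source. The summed counts of the pair were still lower by -0.19 ± 0.04, 4.87 SE from 0. Reads dropped for matching several genes, or counted at other genes, would lower the sum too. The treatment of such reads is not known, so read assignment in that wider sense stays open. In control LPS replicate 4 the log2 CPM of 1190007I07Rik was 1.68, below the other 5, and Gm9855 (1.01) and Tdg also lay near the values of the other label. A scale was set with 0 as the control mean and 1 as the mean of the mice labelled Abca7. Over 15 other genes that differ between the labels the median position of this library was -0.015. Placed the same way, the 11 other controls lay between -0.017 and 0.68 and the 12 labelled Abca7 libraries between 0.30 and 1.39. The chromosome 10 genes left out of that median lay at 0.99 (Gm9855), 0.73 (Tdg) and 1.69 (1190007I07Rik). Single genes among the 15 ran from -0.997 to 0.60, and A930033H14Rik, also on chromosome 10, lay at 0.49. Abca7 was not among the 15 and lay at 0.44. The median of the 15 genes thus places this library with the controls. Gm9855, Tdg and 1190007I07Rik place it with the other label, so a wrong label is not decided.

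The third pattern is the choroid plexus list, which had the largest interaction, a median of -1.91. Choroid plexus tissue carried along with some cortices is in line with these values: the mean of the other 9 markers ranged by at least 1.31 log2 CPM within every group, so that mice of 1 label and 1 stimulus differed among themselves. The difference of these markers between the labels was 1.72 without and -0.43 under LPS, a change of -2.14 ± 0.68. This change is the interaction by which the list was picked, in the same libraries. It therefore cannot test an effect of the genotype that is present whatever the stimulus. In unstimulated control replicate 1 the list mean was 2.58, above the other 5, and in labelled Abca7 LPS replicate 6 it was 0.35, below them. Whether LPS and genotype act together on choroid plexus genes in the tissue itself was not tested.

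The other library values apart from their groups follow, in log2 CPM. Those of Ccl2, Tnf, Gm9855 and Serpina3f come from 0 to 8 counts per library, and Tnf had 1 count in 1 library and 0 in the other 5, so that they differ by a few reads. In unstimulated control replicate 1, Hspa12b was at 2.99, Tdg at 4.70, and the list means at 2.47 for A1 astrocytes, 5.73 for immediate early genes and 0.41 for monocytes. In unstimulated labelled Abca7 replicate 1 the list means were 2.46 for interferon-stimulated genes, 3.05 for MHC class I, 7.02 for astrocytes and 5.63 for heat shock. Unstimulated control replicate 6 had Ccl2 at -4.88 and the endocytosis list at 6.85, and replicate 4 had Tnf at -4.32 and the endothelial identity list at 4.59. Gm9855 was at -3.85 in unstimulated control replicate 3, and Serpina3f at -4.31 in unstimulated labelled Abca7 replicate 2. Control LPS replicate 5 had Cx3cr1 at 3.02 and the meningeal fibroblast list at 2.52, and control LPS replicate 1 the disease-associated microglia list at 3.43. In the LPS mice labelled Abca7, the immediate early list was at 4.99 in replicate 6 and the oligodendrocyte precursor list at 4.99 in replicate 5.

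A set of 18 lists differed between the labels in the LPS effect by the preset test, and 0 of them with an estimated correlation. Besides the choroid plexus list, the median interactions were -0.57 for proinflammatory, -0.35 for interferon-stimulated, -0.086 for LPS recognition, -0.48 for acute-phase, 0.077 for homeostatic microglia, -0.085 for disease-associated microglia, -0.26 for pan-reactive, -0.23 for A1 and -0.29 for A2 astrocytes, -0.28 for MHC class I, -0.21 for complement, -0.32 for endothelial activation, -0.14 for glucocorticoid-responsive, -0.066 for heat shock, -0.054 for astrocyte, -0.10 for oligodendrocyte precursor and -0.34 for ependymal genes. Without labelled Abca7 LPS replicate 4 the proinflammatory value was -0.34, and LPS recognition, at -0.034, lost its camera call (adjusted p = 0.151). With control LPS replicate 4 and unstimulated labelled Abca7 replicate 1 also left out, 15 lists kept the camera call. The proinflammatory value was then -0.24 and that of MHC class I -0.092. Those that lost it were interferon-stimulated (-0.081, camera adjusted p = 0.0757), homeostatic microglia (0.051, 0.0778) and heat shock (-0.036, 0.103). The interaction values of all lists include the difference between the labels without LPS. For the proinflammatory list mean that difference was 0.31 (exact permutation p = 0.0823).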

How the results depend on the processing

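The tests with the Ttr level or the ribosomal share as a covariate, without labelled Abca7 LPS replicate 4, without 3 libraries that stood apart, and with the genotype averaged over both stimuli were chosen after the results were seen. No paired analysis was possible because the replicate numbers follow the order of the series and mark no shared animal or day. Animals of the same age with neighbouring numbers were instead set as a random effect (10 clusters, consensus correlation 0.172), which gave 3970, 2860, 9, 1 and 0 calls in the 5 contrasts in their order in the text. The LPS counts kept within 1.5 times under all other settings but went to 1836 (surrogate variables) and 1626 (Ttr level) in control mice, and to 1270 (surrogate variables) in mice labelled Abca7; without single libraries they ran from 3201 to 4189 and from 2165 to 2841. The genotype effect without LPS called 31 genes with DESeq2, 3 with only the 2 groups compared, 14 with age as a factor, 2 with the Xist level, 95 with surrogate variables, 3 with the Ttr level and 15 without the 3 libraries. It called from 2 (without unstimulated labelled Abca7 replicate 3, among others) to 38 (without unstimulated control replicate 1). The genotype effect averaged over both stimuli, another contrast (57 genes), called from 35 without the filter to 620 with surrogate variables, with 299 for the Ttr level and 111 for the ribosomal share, and from 13 to 122 without single libraries. The genotype effect under LPS called 37 with DESeq2, 1 each with limma-voom, the Xist level and the ribosomal share, 16 with surrogate variables and 2 without the 3 libraries, and 0 or 1 without single libraries (1 without control LPS replicate 4). The interaction called 0 to 7 without single libraries (7 without unstimulated control replicate 1). The Abca7 difference under LPS was 0.26 and past the threshold with DESeq2. The Pearson correlation of the LPS effects was 0.303 without the filter, where genes with few counts enter, 0.957 with the stricter filter, and 0.874 (without unstimulated control replicate 1) to 0.890 without single libraries.

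With the correlation estimated, 13, 13, 0, 0 and 0 lists were called in the 5 contrasts in their order in the text, and fry called 0 in each of the last 3. The Xist level gave 8 lists without LPS, leaving out labelled Abca7 LPS replicate 4 gave 9 under LPS, and the Ttr level gave 3 in the interaction. Signs turned for Mal (-0.017, surrogate variables) and, with the Ttr level, for Kl (-0.051), Clic6 (-0.19), Folr1 (-0.22) and F5 (-0.21), all in the LPS effect in control mice. With the Ttr level the lists that turned had adjusted p of 0.0750 (choroid plexus) and 0.353 (thalamus) in that effect, 0.0432 (disease-associated microglia), 0.0816 (choroid plexus) and 0.870 (ependymal) in the genotype effect without LPS, and 0.657 (disease-associated microglia), 0.861 (astrocyte), 0.00110 (oligodendrocyte), 0.560 (choroid plexus), 0.737 (ependymal) and 0.00000374 (thalamus) in the interaction. The turn of choroid plexus genes follows from a covariate that is one of them; the cause was not tested for the other changes. Over 16285 values of single genes, 15703 had the same call, 416 lost it, 161 gained it and 5 reversed; over 1365 list values these were 1170, 155, 29 and 11. Of the 15703 and the 1170, 354 and 73 changed sign and were past the threshold in neither fit. With at least 48149131 counts per library, depth limits only genes near 0 counts such as Tnf without LPS.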

Other observations

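The Abca7 contrast averaged over both stimuli and the genes in the next paragraph were chosen after their values were seen. Several list members outside the calls above changed with LPS in control mice. Of 23 mouse counterparts of Alzheimer risk genes, which camera did not call as a list (adjusted p = 0.532), 3 rose and 3 fell, 4 and 6 adjusted over the list alone. Ms4a6d rose by 2.70, the myeloid transcription factor gene Spi1 by 0.63 and the endocytic adaptor gene Picalm by 0.24, while Inpp5d, a phosphatase gene of microglia, fell by 0.75, Trem2 by 0.41 and Cd2ap by 0.19. Of the 5 neutrophil markers measured, 2 rose and 1 fell. Camera did not call this list (adjusted p = 0.33) and fry called it higher in control mice (adjusted p = 0.0452) and in mice labelled Abca7 (0.0150). The alarmin genes S100a8 and S100a9 rose by 2.19 and 2.59, and by 1.87 and 2.16 in mice labelled Abca7, while the receptor gene Csf3r fell by 0.32 in control mice. Of 14 extracellular matrix genes (camera adjusted p = 0.812 as a list) 3 rose, the basement membrane collagen genes Col4a1 (0.80) and Col4a2 (0.44) and the fibronectin gene Fn1 (0.37), and 4 had lower values past the threshold, Col1a1 (-0.73), Col1a2 (-0.45), Col5a1 (-0.29) and the collagen chaperone gene Serpinh1 (-0.28). The caveolar gene Cav1 fell by 0.78, and the lipid-related genes Apod and Abca9 changed by 0.72 and -0.93.

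With both stimuli averaged, 57 genes differed between the labels, 32 higher and 25 lower in mice labelled Abca7, and 2406 had an unadjusted p under 0.05. The count ran from 13 (without unstimulated labelled Abca7 replicate 6) to 122 (without control LPS replicate 6) when single libraries were left out. Outside chromosome 10, the lower genes with the smallest p were Plcxd2 (-0.20), the phosphodiesterase gene Pde4d (-0.18), the GABA receptor subunit gene Gabrb2 (-0.19) and the potassium channel gene Kcnh5 (-0.22), and the higher ones Ccdc108 (0.34), Adamts10 (0.23), Thbs3 (0.24) and Akap8 (0.13). The imprinted RNA gene Meg3 was higher by 0.19, and Abca7 itself by 0.21 (adjusted p = 0.0461). The call of Meg3 ended without unstimulated labelled Abca7 replicate 6 (adjusted p = 0.0543), and that of Abca7 without any 1 of 16 of the 24 libraries (0.0539 to 0.105), control LPS replicate 4 among them (0.0639). Spp1 was lower with -0.38, and on chromosome 10 A930033H14Rik was higher by 0.74 while Ano4 (-0.16) and Ntn4 (-0.27) were lower. Of these, Spp1 and Ntn4 lost their calls in 13 of the 24 fits without 1 library and Ano4 in 5 (highest adjusted p 0.0908, 0.0924 and 0.0621); A930033H14Rik and the 8 genes named by smallest p kept theirs in all 24.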
